A study of Homo sapiens with 16 samples.

How the data were processed

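Gene expression was measured in 16 RNA samples from human scalp hair follicles, each on 1 Affymetrix array of 22283 probe sets. The sample titles place 5 arrays in the bulge, 5 in the sub-bulge, 2 in the upper bulge, 2 in the inner bulge and 2 in the suprabulbar region, and give each array a number from 1 to 5. Bulge and sub-bulge have all 5 numbers, and the other groups have numbers 4 and 5. Regions were taken by laser capture, per the series description. RNA was isolated with a small-sample kit, treated with DNase and checked on a Bioanalyzer, then amplified linearly in 2 rounds from a T7 primer and labelled with biotin, per the labels' protocols. What the numbers stand for and how many donors were used are not given in the sources used here, and nothing in the labels says that differently numbered arrays come from separate donors. Arrays may share a donor, so p-values that rest on the spread between these samples, which may be technical, may be too small. Those of gene lists also depend on how far the genes of a list vary together. The number of arrays limits the precision, most of all where a group has 2.

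The deposited table holds 1 linear intensity per probe set and array, and its values show that the authors scaled every array to a common trimmed mean of about 150.0, taken here with 2% of the values left off at each end. The summary algorithm, the scaling software and their versions are not given in the sources used here. A total of 0 columns of per-sample values were left unused. The array medians differed by up to 0.53 on the log2 scale, above the limit of 0.5 that had been set for adding quantile normalization, so the values were quantile normalized with limma, floored at the 10th percentile of all values (an intensity of 6.01, log2 2.59) and log2 transformed. A probe set was kept if its second-highest value over the 16 arrays reached the 60th percentile (91.9, log2 6.52), which left 11519 probe sets for 7489 genes. The 68 control probe sets and 52 probe sets of XIST and Y-linked genes were left out. A fold change understates the difference of a gene with values at the floor, and a gene at the floor on every array of a group has only a bound.

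Probe sets were named through the platform annotation of 2016. Of the 22283 probe sets, 19071 had 1 symbol, 1043 had several and 2169 were unnamed here, controls included; 19059 were found in the table of Entrez identifiers, which changed 0 symbols. Among those kept, 10224 had 1 symbol and 1295 had several or none. A gene was represented by its probe set with 1 symbol and the highest mean over all arrays.

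The 5 comparisons set the bulge against each other group and against the mean of the other 4 groups. They were contrasts of 1 linear model with a term per group over all 16 arrays (limma lmFit and eBayes, two-sided, 11 residual degrees of freedom, prior 3.82), with Benjamini-Hochberg adjustment over the probe sets and a threshold of 0.05. Differences are given as log2 bulge minus the other group with the model's standard error (SE). Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists of each comparison, and again with an estimated correlation. The preset takes the genes of a list as nearly independent, while the estimate was 0.273 for proliferation and 0.302 for fibroblast genes. The p-values at the preset may therefore be far too small. Members past the threshold were counted over all genes and adjusted over the list alone. The 31 lists hold 2 sets of genes that the study selected on these samples, hair follicle, epidermal and adhesion genes, cell cycle genes, markers of other cell types, and signalling, stress, immune and metabolic genes. Some genes belong to several lists, so the lists are not independent of each other.

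Groups, tests, lists, the naming rule and most alternatives were chosen before the data were examined. The naming rule took, against the sub-bulge, the 12 largest and 12 smallest log2 differences past the threshold with the same sign in all 5 same-numbered pairs, and in the other comparisons the 10 largest and 10 smallest past it. Where under 5 passed in a direction, it took the 5 genes with the smallest unadjusted p, given as values. It added the members of the study's 2 sets, KRT15, KRT19 and up to 4 members of each list with the smallest p. The genes printed are part of those the rule names and were chosen from them after their values, and their changes of sign under the alternatives, were seen; applying the rule also to the model with the replicate number as a block was added after seeing the data.

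The numbers were checked for pairing by correlating the deviations of same-numbered bulge and sub-bulge arrays from their group means. The correlations were 0.36, 0.35, 0.36, 0.20 and 0.42, all above the preset limit of 0.1, so the number was taken to pair these arrays, although the best partner of bulge array 4 was not its own. Over all 5 groups, arrays of number 4 correlated at 0.12 to 0.50 and arrays of number 5 at 0.05 to 0.42, the lowest below that limit, so the pairing is less sure outside the bulge and sub-bulge. The pairing rests on the numbers in the titles and on this check. A model with the number as a fixed block left 7 residual degrees of freedom; a random block had a consensus correlation of 0.311.

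Alternatives were the deposited values without quantile normalization, no filter and a stricter filter (75th percentile), a floor at the 30th percentile, only the groups compared, a trended and robust prior, array weights, a minimum of 2-fold, the mean of a gene's probe sets, both blocks, and leaving out each array in turn. Alternatives chosen after seeing the data were the block on the 10 bulge and sub-bulge arrays alone, a model without the 2 inner-bulge arrays, each array's mean log2 3' over 5' ratio of ACTB and GAPDH as a covariate, and lists without the members they share with the genes the study picked.

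The method was tested on simulated values for the 11519 probe sets with 100 changed by 2-fold and 100 by 4-fold. Against the sub-bulge it called 44 and 87 of them with 5 false calls, against the upper bulge 12 and 70 with 6, against the inner bulge 13 and 77 with 6, against the suprabulbar region 22 and 77 with 2, and against the mean of the others 60 and 92 with 7, and 0 had the wrong sign. A list of 20 members shifted by 0.5 was called in all 5 comparisons and 0 of 30 unshifted lists were. These simulated values do not carry the correlation between genes of the real ones, where camera called lists in most splits of the arrays other than the real one, as the closing paragraphs give. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.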

Results

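Expression in the bulge of human scalp hair follicles, the part of the outer root sheath known to hold epithelial stem cells, was set against other captured regions of the follicle. The aim was to find the genes that set the bulge apart. There were 5 bulge, 5 sub-bulge, 2 upper-bulge, 2 inner-bulge and 2 suprabulbar arrays. The median deposited intensity of an array lay between 53.5 and 77.5, and 0 pairs of arrays held identical values.

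The inner-bulge arrays stood apart. Over the probe sets kept, the 14 other arrays correlated with each other at 0.794 to 0.947. The 2 inner-bulge arrays correlated with those at 0.657 to 0.810 and with each other at 0.858. The mean log2 3' over 5' ratio of ACTB and GAPDH, higher in more degraded or shortened RNA, was 4.71 ± 0.34 in the bulge and 4.64 ± 0.52 in the sub-bulge (SD, n = 5 and 5, two-sided exact permutation p = 0.794). It was 4.61 ± 0.61 in the upper bulge, 4.78 ± 0.40 in the inner bulge and 3.97 ± 0.01 in the suprabulbar region (SD, n = 2 each).

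**Figure D1:**
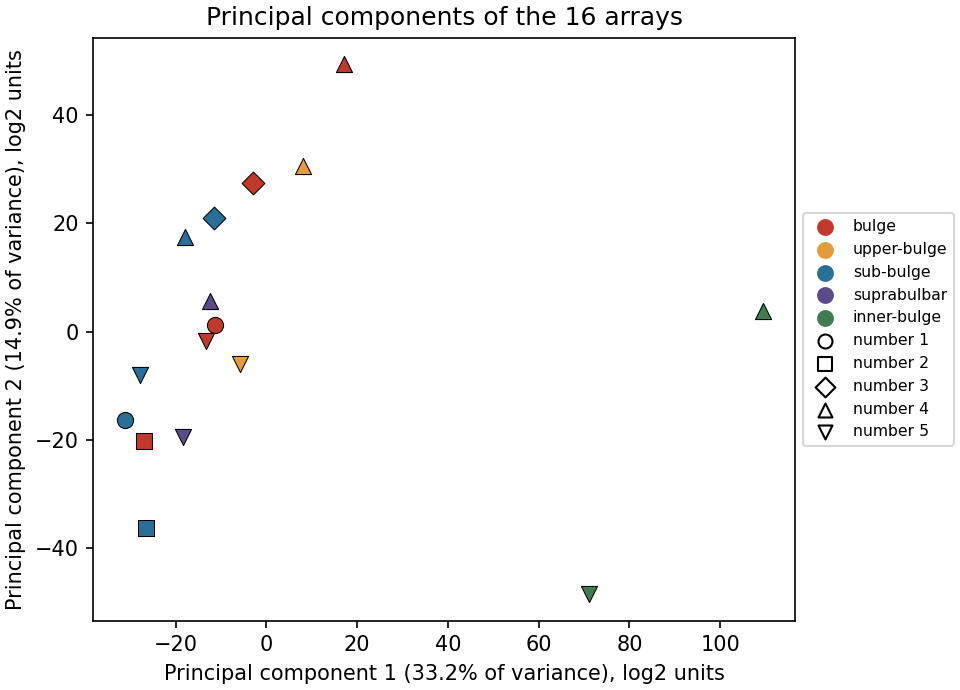
Principal components of the log2 intensities of the 16 arrays, with 33.2% of the variance on the horizontal and 14.9% on the vertical axis; colours are groups and marker shapes are the numbers 1 to 5. The 2 inner-bulge arrays lie far to the right of the other 14.

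ALAD, an enzyme of haem synthesis, was lower in the bulge than in the sub-bulge (-1.96 ± 0.23, SE, n = 5 and 5, adjusted p = 0.00435). COMP, a matrix glycoprotein of cartilage and tendon, was lower too (-2.91 ± 0.46, adjusted p = 0.0328). NEBL, which encodes the actin-binding protein nebulette, was higher (1.46 ± 0.23, adjusted p = 0.0328), as was MOXD1, a member of the copper monooxygenase family (1.80 ± 0.30, adjusted p = 0.0486). Each of the 4 differed the same way in 5 of 5 same-numbered pairs. None of the 4 passed against the upper bulge, so they do not set the bulge apart from every region. On upper-bulge arrays 4 and 5, NEBL (log2 10.21 and 10.46) and MOXD1 (9.53 and 9.33) were above the same-numbered bulge arrays. ALAD (7.39 and 6.92) and COMP (7.25 and 5.64) were below them. Against the sub-bulge 6 of 11519 probe sets passed in limma, 4 higher and 2 lower. The other 2 were further probe sets of TOX3 (1.83 ± 0.28, adjusted p = 0.0328) and PHLDA1 (1.60 ± 0.22, adjusted p = 0.0156), which do not represent these genes here and were chosen after their values were seen. The probe sets that represent TOX3 (2.46 ± 0.48, adjusted p = 0.0784) and PHLDA1 (1.00 ± 0.45, adjusted p = 0.727) did not pass. The deposited values without quantile normalization gave 16 probe sets, 8 higher and 8 lower.

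With the replicate number as a block, 66 probe sets passed, 32 higher and 34 lower, and these included all 6. For genes that passed only with the block, the adjusted p without and with it follows each value. On the higher side, DIO2, the deiodinase that activates thyroid hormone, was at 2.12 ± 0.41 (0.0784 and 0.00619). SCNN1A, a subunit of the epithelial sodium channel, was at 2.01 ± 0.36 (0.0516 and 0.0246), the oestrogen receptor ESR1 at 1.49 ± 0.31 (0.1 and 0.0227) and TOX3 at 2.46 ± 0.48 (0.0784 and 0.0258). On the lower side, the growth factor FGF18 was at -2.16 ± 0.43 (0.0784 and 0.00619) and the Wnt ligand WNT5A at -1.76 ± 0.41 (0.169 and 0.0136). The vitamin D hydroxylase CYP27B1 was at -1.44 ± 0.27 (0.0649 and 0.0264) and the ubiquitin ligase TRIM9 at -1.73 ± 0.30 (0.0516 and 0.00296). All of these pointed the same way in 5 of 5 pairs. With the block on the 10 arrays compared alone, 32 probe sets passed, 17 higher and 15 lower. DIO2, SCNN1A, FGF18 and TRIM9 passed there, and ESR1 (0.0705), TOX3 (0.0852), WNT5A (0.0513) and CYP27B1 (0.0902) did not.

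**Figure D2:**
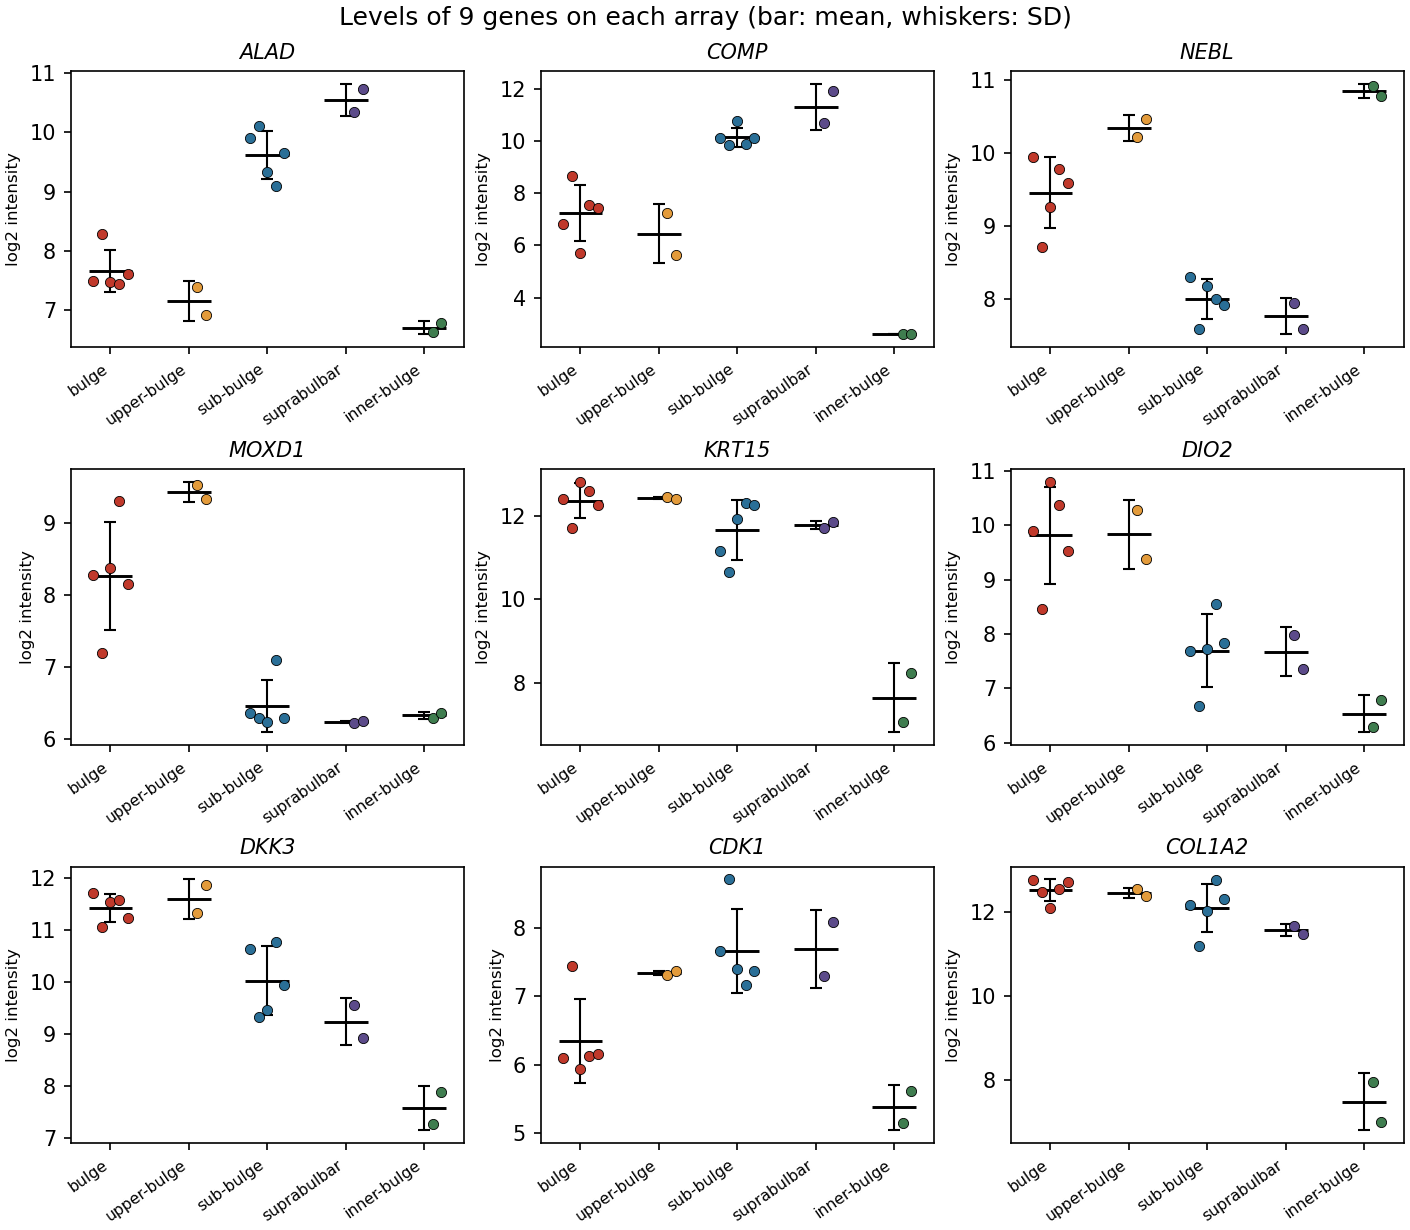
Log2 intensity of ALAD, COMP, NEBL, MOXD1, KRT15, DIO2, DKK3, CDK1 and COL1A2 on each of the 16 arrays by group, each point 1 array, with bars at the group mean and whiskers of 1 SD. ALAD and COMP were lower and NEBL and MOXD1 higher in the bulge than in the sub-bulge.

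Of 38 measured proliferation genes, 36 were below 0 against the sub-bulge, with a median of -0.50, and the list was lower in the bulge (adjusted p = 2.17e-13, and 0.148 with an estimated correlation). None passed over all genes in limma, and 1 was lower adjusted over the list alone. The mitotic kinase CDK1 was at -1.31 ± 0.33 (adjusted p = 0.228 without and 0.00619 with the block), the spindle checkpoint kinase BUB1B at -0.98 ± 0.30 and CDKN3 at -0.73 ± 0.24. All 8 genes that the study is known to have picked as raised in the bulge were above 0, with a median of 0.99 (adjusted p = 6.98e-10, and 0.021 with an estimated correlation). With the block and an estimated correlation the adjusted p was 0.111, so the call ended. The study chose these genes on these samples, so this is not independent evidence. Among them, 5 were higher adjusted over the list alone. Not all of the 8 were higher in every pair. PHLDA1 was lower in the bulge in pair 2 (log2 7.15 and 7.48) and pair 4 (6.71 and 7.09), and WIF1 in pair 4 (10.09 and 10.41). The basal keratin KRT15 was at 0.70 ± 0.33 (adjusted p = 0.75). It was higher in 5 of 5 pairs, though nearly level in pair 5 (log2 12.27 in the bulge and 12.25 in the sub-bulge). The membrane glycoprotein CD200 was at 0.98 ± 0.34. None of their representing probe sets passed over all genes without the block, and DIO2 and DKK3 passed with it (0.00619 and 0.0389), DKK3 not with the block on the 10 arrays alone (0.0596).

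Upper-follicle markers were higher as a list, 6 of 8 above 0 with a median of 0.41 (adjusted p = 0.00228, and 0.136 with an estimated correlation). The protease inhibitor CST6 was among them (2.32 ± 0.44, adjusted p = 0.077 without and 0.0158 with the block, and 0.0572 with the block on the 10 arrays alone). FGF pathway genes were lower, 7 of 10 below 0 with a median of -0.12 (adjusted p = 0.00326, and 0.0917 with an estimated correlation). Of these 3 were lower adjusted over the list alone, and the receptor FGFR3 was at -0.71 ± 0.21. Epidermal differentiation genes were higher, 12 of 17 above 0 (adjusted p = 0.0154, and 0.258 with an estimated correlation). MHC class I genes were higher, 9 of 11 above 0 (adjusted p = 0.0321, and 0.258 with an estimated correlation), as were glycolysis genes, 15 of 17 above 0 (adjusted p = 0.041, and 0.465 with an estimated correlation). The deposited values ended the calls of MHC class I (0.0763) and glycolysis genes (0.218). With no filter on dim probe sets the FGF (0.0507) and glycolysis calls (0.0762) ended. Fibroblast markers passed only with the block (16 of 21 above 0, median 0.31, adjusted p = 0.0571 without and 0.0439 with it, but 0.689 with the block and an estimated correlation). Two-sided exact permutation tests of each list's mean per array gave unadjusted p = 0.00794 for the study's raised genes and FGF genes. They gave 0.0238 for proliferation and upper-follicle genes, and 0.127, 0.0873 and 0.143 for epidermal differentiation, MHC class I and glycolysis genes. Sign flips within the 5 pairs gave 0.0625 for all 7 of these lists, the smallest possible. Of the lists that camera did not call, Wnt target genes also gave 0.00794 in the permutation test and 0.0625 by sign flips. Wnt inhibitors, not called either, gave 0.0238 and 0.125.

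ALAD passed with any 1 array left out. NEBL ended without bulge array 1, 3, 4 or 5, sub-bulge array 2, 3, 4 or 5 or inner-bulge array 4 or 5 (adjusted p from 0.0543 to 0.13). COMP ended without any of these or sub-bulge array 1 (0.0543 to 0.149), and MOXD1 without any 1 array except bulge array 2 (0.0583 to 0.152). All 3 also ended with only the 10 arrays compared (NEBL 0.117, COMP 0.0711, MOXD1 0.128) and with no filter on dim probe sets (0.106, 0.117 and 0.117). COMP ended with the block on these 10 arrays alone (0.0718), and all 3 without the 2 inner-bulge arrays (0.0543 for NEBL). The count of 6 became 1 without bulge array 1 or 3. It was 2 without sub-bulge array 3 or 4 or either inner-bulge array, 3 without bulge array 4 or 5 or sub-bulge array 2, and 42 without bulge array 2. Epidermal differentiation genes ended without bulge array 1 (0.0542), sub-bulge array 3 (0.108) or bulge array 5 (0.0912). MHC class I genes ended without sub-bulge array 1 (0.114) or 2 (0.0951) or bulge array 4 (0.156) or 5 (0.0912). Glycolysis genes ended without the same arrays (0.117, 0.211, 0.156 and 0.169).

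The bulge had lower epidermal differentiation genes than the upper bulge, 15 of 17 below 0 with a median of -0.72 (n = 5 and 2, adjusted p = 5.05e-07, and 0.0319 with an estimated correlation). Cholesterol synthesis genes were lower too, 13 of 14 below 0 with a median of -0.44 (adjusted p = 1.02e-05, and 0.0319 with an estimated correlation). Examples are S100A8, an antimicrobial calcium-binding protein (-3.95 ± 0.90), S100A7 (-3.54 ± 1.33) and HMGCS1, an enzyme of the mevalonate pathway (-1.18 ± 0.40), none of which passed alone. All 38 proliferation genes were below 0, with a median of -0.62, RRM2 at -1.05 ± 0.38 and BUB1B at -1.07 ± 0.39 (adjusted p = 4.07e-15, and 0.087 with an estimated correlation). Sebaceous lipid genes were lower, 9 of 10 below 0 with SCD at -2.13 ± 0.50 and FASN at -0.90 ± 0.32 (adjusted p = 0.000313, and 0.0613 with an estimated correlation).

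Smooth muscle markers were higher than in the upper bulge, 7 of 9 above 0 with MYH11 at 2.62 ± 0.72 (adjusted p = 0.00337, and 0.246 with an estimated correlation). Fibroblast markers were higher, 16 of 21 above 0 with FBN1 at 0.89 ± 0.50 (adjusted p = 0.0222, and 0.437 with an estimated correlation). FGF genes were higher, 9 of 10 above 0 (adjusted p = 0.00337, and 0.0613 with an estimated correlation), as were hedgehog genes, 4 of 5 above 0 (adjusted p = 0.0388, and 0.14 with an estimated correlation). The block ended the hedgehog call (0.145). Glycolysis genes were lower, 14 of 17 below 0 (adjusted p = 0.00251, and 0.225 with an estimated correlation), and the block ended that call (0.269). Oxidative phosphorylation genes were lower, 26 of 32 below 0 (adjusted p = 0.00292, and 0.339 with an estimated correlation).

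In limma 1 probe set passed against the upper bulge, for the chromatin protein ING1 (2.43 ± 0.34, adjusted p = 0.0466 without and 0.17 with the block). Its other probe set had the opposite sign. At an unadjusted p under 0.05 there were 319 probe sets. With the block 0 passed in limma, with 547 at an unadjusted p under 0.05, and with a random block 1. The R-spondin receptor LGR5 (1.60 ± 0.35), the keratins KRT75 (-1.91 ± 0.39) and KRT15 (-0.07 ± 0.44) did not pass. Of the 8 genes the study picked as raised, 6 were below 0 against the upper bulge, with a median of -0.09. That list did not pass camera (adjusted p = 0.259). The call of ING1 ended without bulge array 1, 2, 3 or 4, any sub-bulge array or either upper-bulge array (adjusted p from 0.0715 to 0.389), and ended in the deposited values (0.224). It also ended with the mean of a gene's probe sets (0.999), no filter (0.057), the higher floor (0.0773), only the groups compared (0.649), array weights (0.0931) and the covariate (0.067). Without these arrays the limma count was 0, with 240 to 461 probe sets at an unadjusted p under 0.05, and it was 2 without bulge array 5 or either inner-bulge array.

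Several lists rested on single arrays in this comparison. Fibroblast markers ended without bulge array 1 (0.0906), 4 (0.0527) or 5 (0.144) or upper-bulge array 5 (0.33). Smooth muscle markers ended without bulge array 1 (0.0569) or upper-bulge array 4 (0.208). Hedgehog genes ended without bulge array 2 (0.0806), 3 (0.104) or 4 (0.0944) or upper-bulge array 4 (0.208) or 5 (0.167). Without upper-bulge array 5 the FGF (0.114) and cholesterol synthesis genes (0.128) ended. With no filter on dim probe sets the sebaceous lipid (0.0513), hedgehog (0.0513) and FGF calls (0.071) ended. Without upper-bulge array 4 the glycolysis (0.467) and oxidative phosphorylation genes (0.193) did.

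Of 21 fibroblast markers, 20 were higher in the bulge than in the inner bulge (median 3.38, n = 5 and 2, adjusted p = 1.25e-17, and 0.0311 with an estimated correlation). Among them were the collagen COL1A2 (5.03 ± 0.35) and the receptor PDGFRA (5.09 ± 0.52). The collagen COL3A1 (5.82 ± 0.79) and the proteoglycan LUM (5.85 ± 0.66) were each at the floor on 1 inner-bulge array, so their differences are understated. Of 17 epidermal differentiation genes, 13 were lower (median -2.81, adjusted p = 1.8e-09, and 0.0105 with an estimated correlation). Among them were the cornified envelope proteins IVL (-3.16 ± 0.31) and SPRR1B (-4.45 ± 0.52) and the corneodesmosome protein CDSN (-5.46 ± 0.76). TNS3, a focal adhesion protein, was at the floor on both inner-bulge arrays, so its difference is at least 7.26 (adjusted p = 4.12e-09).

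KRT15 was higher in the bulge than in the inner bulge (4.72 ± 0.44, adjusted p = 6.08e-06). It is 1 of the 8 genes the study picked as raised, of which 6 were higher, with the Wnt antagonists WIF1 (5.64 ± 0.92) and DKK3 (3.85 ± 0.38) and with CD200 (1.88 ± 0.45). CD200 ended without inner-bulge array 4 (0.237) and with only the groups compared (0.0558). That list passed (adjusted p = 0.000162, and 0.0429 with an estimated correlation), and again is not independent evidence. Of the 4 genes the study picked as lowered, 1 was lower (CD24, -2.76 ± 0.36), 1 was higher (MCAM, 1.10 ± 0.30, adjusted p = 0.0201) and 2 did not pass, and the list did not pass (adjusted p = 0.434). MCAM ended without inner-bulge array 4 (0.301), with only the groups compared (0.0886) and with array weights (0.0514). Of 22 genes known from the mouse bulge, 13 were higher (adjusted p = 1.89e-08, and 0.00117 with an estimated correlation), with LGR5 at 4.03 ± 0.35 and the Wnt antagonist SFRP1 at 3.00 ± 0.27. The mouse bulge list did not pass camera against the sub-bulge (median 0.05, adjusted p = 0.753) or the upper bulge (median -0.004, adjusted p = 0.867). Of 14 basal adhesion genes, 8 were higher (adjusted p = 5.21e-05, and 0.0429 with an estimated correlation), with the integrin ITGA6 at 2.49 ± 0.25 and the laminin chain LAMB3 at 2.57 ± 0.43.

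Of 10 Wnt inhibitors, 7 were higher and 1 was lower in the bulge (adjusted p = 0.000186, and 0.0311 with an estimated correlation). They include WIF1 and DKK3 of the study's list, and without these 2 the list also passed (0.00668, and 0.0429 with an estimated correlation). BMP and TGF-beta genes were higher in 9 of 20 (adjusted p = 0.00422, and 0.0311 with an estimated correlation), with LTBP2 at 2.21 ± 0.21. Hedgehog genes were higher in 2 of 5 (adjusted p = 0.00668, and 0.0429 with an estimated correlation), with the transcription factor GLI2 at 1.76 ± 0.29. Sebaceous lipid genes were lower in 5 of 10 (adjusted p = 0.000262, and 0.0429 with an estimated correlation), with the desaturase SCD at -2.75 ± 0.50 and FA2H at -1.89 ± 0.37. With the block and an estimated correlation together, the calls against the inner bulge ended for the study's list (0.0833), basal adhesion (0.0833), Wnt inhibitors (0.0709), BMP and TGF-beta (0.0577), hedgehog (0.0833) and sebaceous lipid genes (0.0518). Fibroblast (0.031), epidermal differentiation (0.00826) and mouse bulge genes (0.00826) passed there.

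Further lists passed against the inner bulge at the preset correlation alone. Proliferation genes were higher in 13 of 38 (adjusted p = 0.0004, and 0.363 with an estimated correlation), with the replication helicase subunit MCM6 at 1.84 ± 0.32 and thymidylate synthase TYMS at 1.81 ± 0.31. Cholesterol synthesis genes were lower in 5 of 14 (adjusted p = 0.00291, and 0.0532 with an estimated correlation), with MSMO1 at -1.53 ± 0.34. Smooth muscle markers were higher in 5 of 9 (adjusted p = 0.00668, and 0.209 with an estimated correlation). FGF genes were higher in 6 of 10 and lower in 1 (adjusted p = 0.0263, and 0.0988 with an estimated correlation), with SPRY2 at 3.13 ± 0.53. Immediate early genes were lower in 4 of 19 and higher in 1 (adjusted p = 0.0222, and 0.135 with an estimated correlation), with EGR3 at -2.25 ± 0.41 and KLF4 at -1.46 ± 0.25. Ribosomal proteins were higher in 3 of 38 (adjusted p = 0.00597, and 0.114 with an estimated correlation). The list of companion layer and wound keratin genes, called companion layer genes below, was lower (adjusted p = 0.0404, and 0.102 with an estimated correlation). Of its 3 measured members 1 passed, the keratin KRT16, and the block ended the list's call (0.0986). The deposited values ended the calls of companion layer (0.0562) and immediate early genes (0.0534). The call of companion layer genes also ended with the 3' over 5' ratio as a covariate (0.053). FGF genes ended with the stricter filter (0.155) and with the mean of a gene's probe sets (0.121). MHC class I genes passed only with the block (adjusted p = 0.105 without and 0.0169 with it, but 0.217 with the block and an estimated correlation).

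In limma 1927 of 11519 probe sets passed against the inner bulge, 1254 higher and 673 lower. The 3' over 5' ratios of the 2 inner-bulge arrays (4.50 and 5.07) lay within those of the other arrays (3.96 to 5.25). Among markers of other cell types than fibroblasts and smooth muscle, whose lists passed as given above, 3 of 9 melanocyte genes were higher. Of 15 immune genes 3 were higher and 1 was lower. Neither the melanocyte nor the immune list passed (adjusted p = 0.327 and 0.949). The count was 900 without inner-bulge array 4. Without inner-bulge array 5 the smooth muscle (0.119), FGF (0.119), immediate early (0.106), ribosomal protein (0.0653) and companion layer genes (0.0985) ended. Immediate early genes also ended without bulge array 4 (0.0505). Companion layer genes also ended without bulge array 2 (0.0506) or 3 (0.0575) or inner-bulge array 4 (0.073).

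ALAD was lower in the bulge than in the suprabulbar region (-2.89 ± 0.30, n = 5 and 2, adjusted p = 0.00112). EHD3, a protein of endosomal recycling (-2.33 ± 0.29, 0.00402), COMP (-4.06 ± 0.61, 0.0172) and TRIM9 (-2.59 ± 0.40, 0.0181) were lower too. DKK3 (2.19 ± 0.38, 0.0291) and TOX3 (3.90 ± 0.63, 0.0195) were higher. All 38 proliferation genes were below 0, with a median of -0.89 and the helicase subunit MCM2 at -1.38 ± 0.37 (adjusted p = 4.52e-19, and 0.057 with an estimated correlation), and 13 were lower adjusted over the list alone. Fibroblast markers were higher, 19 of 21 above 0 with a median of 0.96 (adjusted p = 1.8e-09, and 0.118 with an estimated correlation), and 9 were higher adjusted over the list alone.

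The 8 genes that the study picked as raised were all above 0 against the suprabulbar region, with a median of 1.09 (adjusted p = 3.6e-09, and 0.0301 with an estimated correlation). With the block and an estimated correlation the adjusted p was 0.0688, so the call ended, and the study chose these genes on these samples. DKK3 passed over all genes and 6 passed adjusted over the list alone. Upper-follicle markers were higher, 7 of 8 above 0 with a median of 0.57 (adjusted p = 0.000133, and 0.057 with an estimated correlation). Wnt inhibitors were higher, 8 of 10 above 0 with WIF1 at 3.29 ± 0.92 (adjusted p = 0.000133, and 0.057 with an estimated correlation), but WIF1 and DKK3 are also among the genes the study picked, and without these 2 the call ended (0.0543). Genes known from the mouse bulge passed only with the block (adjusted p = 0.0717 without and 0.0226 with it, but 0.0852 with the block and an estimated correlation). FST is in both that list and the study's, and without FST the block gave 0.0781.

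In limma 21 probe sets passed against the suprabulbar region, 10 higher and 11 lower, and 115 with the block, 56 higher and 59 lower, including all 21. The suprabulbar arrays had the lowest 3' over 5' ratios, and with that ratio as a covariate 6 passed, 5 of them among the 21. The covariate ended COMP (0.0723), DKK3 (0.0781) and TOX3 (0.0508). With no filter on dim probe sets the calls of COMP (0.0533), TRIM9 (0.0533), DKK3 (0.0823) and TOX3 (0.0735) ended. With only the groups compared COMP (0.103), TRIM9 (0.0844) and DKK3 (0.0514) did. Without suprabulbar array 5 the count was 3, and EHD3 (0.0918), COMP (0.225), TRIM9 (0.225), DKK3 (0.407) and TOX3 (0.285) ended. Without suprabulbar array 4 it was 11, and TRIM9 (0.0777), DKK3 (0.0828) and TOX3 (0.0713) ended. It was 7 without bulge array 1, 8 without bulge array 3, 10 without bulge array 5 and 49 without bulge array 2. DKK3 also ended without bulge array 1 (0.0791), 3 (0.0808), 4 (0.0568) or 5 (0.0634) or sub-bulge array 5 (0.0547), and TOX3 without bulge array 1 (0.0578), 3 (0.0533) or 5 (0.0523).

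COL14A1 (1.85 ± 0.26, n = 5 and 11, adjusted p = 0.00537), COL1A2 (1.61 ± 0.23, 0.00537) and DKK3 (1.82 ± 0.25, 0.00537) were higher in the bulge than in the mean of the other 4 groups. In limma 75 probe sets passed, 72 higher and 3 lower, and 162 with the block, 133 higher and 29 lower. In a model without the 2 inner-bulge arrays, chosen after seeing the data, 0 passed in limma, with 631 at an unadjusted p under 0.05. The adjusted p there was 0.643 for COL14A1, 0.926 for COL1A2 and 0.49 for DKK3. The count of 75 became 20 without bulge array 1, 42 without bulge array 3, 39 without bulge array 4 and 33 without bulge array 5. It was 40 without upper-bulge array 4 and 148 without inner-bulge array 5.

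Fibroblast markers were higher than in the mean of the others in 5 of 21, and in 18 adjusted over the list alone (adjusted p = 2.87e-23, and 0.0104 with an estimated correlation). Wnt inhibitors were higher in 2 of 10 (adjusted p = 1.12e-06, and 0.00998 with an estimated correlation), DKK3 of the study's list among them, and also passed without DKK3 and WIF1 (0.00105, and 0.0165 with an estimated correlation). The genes the study picked as raised were higher in 3 of 8 (adjusted p = 1.45e-09, and 0.00998 with an estimated correlation), which is not independent evidence. These 3 lists also passed without the inner-bulge arrays, but Wnt inhibitors without DKK3 and WIF1 were not tested there. Wnt inhibitors did not pass camera against the sub-bulge (adjusted p = 0.167, and 0.936 without these 2 genes). They did not pass against the upper bulge either (0.62 and 0.526). Mouse bulge genes were higher in 4 of 22 (adjusted p = 1.43e-08, and 0.00109 with an estimated correlation), with GAS1 at 1.07 ± 0.18, which ended without bulge array 1 (0.0628) and without the inner-bulge arrays (0.893). Basal adhesion genes were higher in 1 of 14 (adjusted p = 8.22e-05, and 0.0494 with an estimated correlation), BMP and TGF-beta genes in 1 of 20 (adjusted p = 0.00103, and 0.0128 with an estimated correlation) and hedgehog genes in 1 of 5 (adjusted p = 0.00335, and 0.0318 with an estimated correlation). The BMP and TGF-beta gene past the threshold was LTBP1 and the hedgehog gene was GAS1, and both are also counted among the mouse bulge genes. With the block and an estimated correlation together, the calls of basal adhesion (0.075) and hedgehog genes (0.096) ended. Epidermal differentiation genes were lower in 1 of 17 (adjusted p = 5.9e-07, and 0.0128 with an estimated correlation), and cholesterol synthesis genes were lower as a list (adjusted p = 0.000496, and 0.0318 with an estimated correlation).

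Proliferation genes were lower than in the mean of the others, 31 of 38 below 0 (adjusted p = 4.83e-06, and 0.232 with an estimated correlation), and sebaceous lipid genes were lower (adjusted p = 0.00139, and 0.0541 with an estimated correlation). Smooth muscle markers were higher (adjusted p = 0.00267, and 0.178 with an estimated correlation), as were ribosomal proteins (adjusted p = 0.0155, and 0.178 with an estimated correlation). The block ended the call of ribosomal proteins (0.148), as did leaving out bulge array 2 (0.0536) or 3 (0.0732) or inner-bulge array 5 (0.0565). Without the 2 inner-bulge arrays the calls of 9 lists ended: mouse bulge (0.245), basal adhesion (0.496), epidermal differentiation (0.624), sebaceous lipid (0.429), smooth muscle (0.0774), BMP and TGF-beta (0.245), hedgehog (0.336), cholesterol synthesis (0.0774) and ribosomal proteins (0.429). Melanocyte genes (0.0847 without and 0.0474 with it) and MHC class I genes (0.0766 and 0.00163) passed only with the block, but not with the block and an estimated correlation (0.225 and 0.12).

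**Figure D3:**
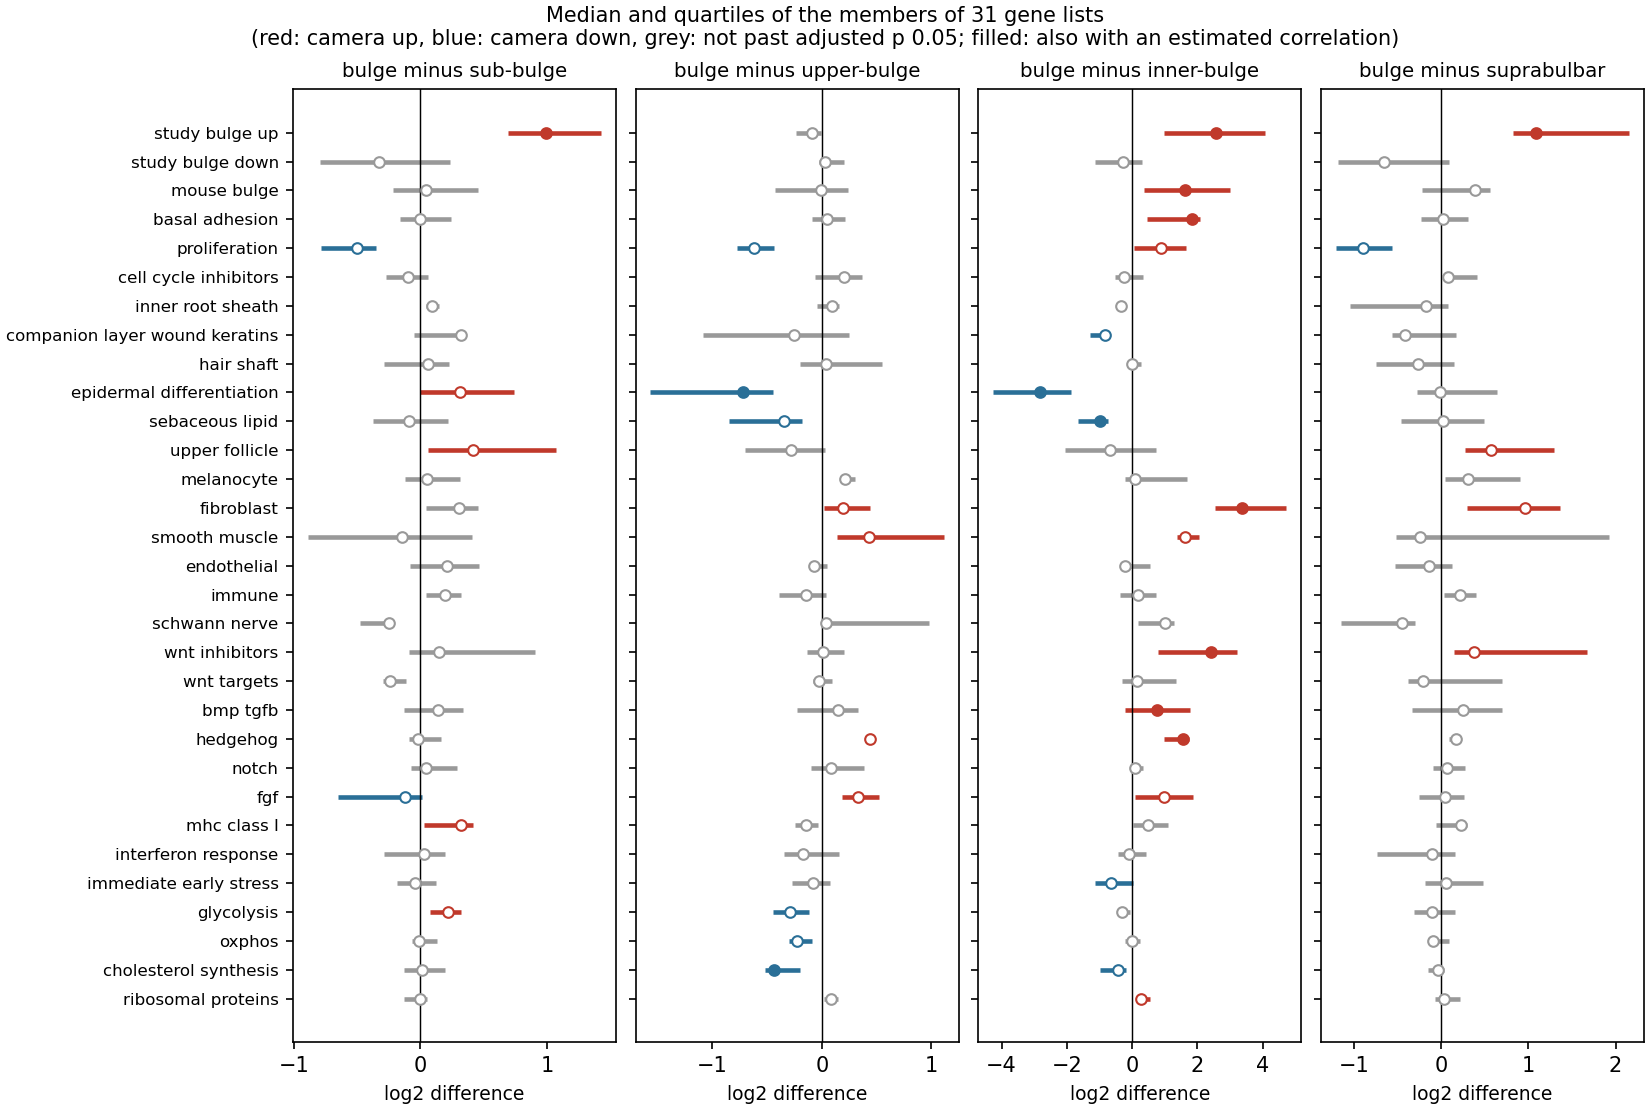
Median and quartiles of the log2 difference, bulge minus the other group, of the measured members of the 31 gene lists in 4 comparisons; red lists were called higher, blue lower, grey not, and filled points also passed with an estimated correlation. The largest shifts lie against the inner bulge, with fibroblast markers at 3.38 and epidermal differentiation genes at -2.81.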

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

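Of the tests here, those of array scaling and of hair shaft genes were chosen after the result was seen, and both kinds of splits within each number were added after the other splits had been seen, with what they would show written down before they were run.

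In 12 of 154 sets of 5 values, drawn from quality values, list means and the genes kept for the text, 1 array lay farther from the rest than chance allows in about 1 of 20 sets (7.7 of these), the critical gap being 0.71 of the range. MOXD1 was at log2 7.09 on sub-bulge array 4 (the other 4 from 6.23 to 6.37) and FST at 7.36 on the same array (6.84 to 6.99). ALAD was at 8.28 on bulge array 2 (7.44 to 7.61) and CDK1 at 7.43 on that array (5.93 to 6.15). On sub-bulge array 2, TOX3 was at the floor of 2.59 (4.99 to 5.96), MCAM at 10.06 (9.42 to 9.59), CDKN3 at 7.68 (7.07 to 7.13) and the mean of the immediate early list at 7.68 (7.94 to 8.04). FGFR3 was at 10.22 on bulge array 4 (10.78 to 10.99) and its log2 ACTB 3' over 5' ratio at 4.79 (5.59 to 5.78). The mean of the endothelial list was 5.48 on bulge array 3 (6.50 to 6.82) and that of the ribosomal list 12.59 on sub-bulge array 4 (12.64 to 12.66).

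Fibroblast genes were higher in the bulge than in the inner bulge, with COL1A2 at log2 12.53 and 7.49, DCN at 11.01 and 8.46 and COL3A1 at 10.44 and 4.62. With the deposited values the list's mean was 3.33 against 3.44 (camera adjusted p = 1.89e-18), so the difference was present under both ways of scaling. Moving to the deposited values shifted the median difference against the inner bulge by only -0.048 log2. This swap could hardly have removed the list's difference, so it does not decide on other faults of scaling. Over the 14 other arrays the 21 members varied together within groups at a mean correlation of 0.357 (0.182 with the replicate block removed). This was above 100% of 1000 matched lists (95th percentile 0.0591), as predicted for connective tissue cells captured in differing amounts. The matched lists held random genes, so any list of genes regulated together could exceed them. The inner-bulge arrays were not among the 14. The test therefore cannot tell whether capture differed. A regional difference of the sheath itself was not tested and stays open.

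Proliferation genes were lower in the bulge than in the sub-bulge. With the 3' over 5' ratio as a covariate the list's mean was -0.55, as without it (camera adjusted p = 3.66e-12, and 0.187 with an estimated correlation). Bulge and sub-bulge had similar mean ratios (4.71 ± 0.34 and 4.64 ± 0.52, SD), so this covariate could move the mean only little. The test therefore cannot decide on RNA degradation. Whether hair shaft cells were captured below the bulge could not be told from the 11 hair shaft genes. Of these 6 were above and 5 below 0, with a median of 0.0636 and an SD of 0.854. Whether the difference belongs to the regions themselves or to capture and processing was not tested and stays open.

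The inner-bulge arrays stood apart from the others. With the deposited values 1646 probe sets passed, against 1927, so the gap was present under both ways of scaling. The move to these values shifted the median difference by only -0.048 log2 and could hardly have removed the gap. With the 3' over 5' ratio as a covariate 2418 passed. Inner-bulge and bulge arrays had similar mean ratios (4.78 and 4.71), so this covariate cannot decide on RNA degradation. Whether the gap belongs to the regions themselves or to capture and processing was not tested and stays open.

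Other splits of the arrays were drawn to ask how often chance gives as much. Since the numbers pair the arrays, the real split against the sub-bulge is compared with the splits that part all 5 pairs. These number 16, too few for a share under 0.05. They gave 1 probe set at most besides the real 6 and 6 lists besides the real 7, and with the replicate block 0 probe sets besides the real 66 (1 of 16 as large, the real one). Of 100 splits of the 10 arrays that ignore the pairs, most of which put both arrays of a pair in 1 group, 2 gave as many probe sets (real 6, highest other 9) and 6 as many lists (real 7, highest other 9). For gene lists chance cannot be excluded by these splits, and for probe sets they do not carry the pairing, so no claim is made from them. Camera often called lists here: in 11 of the 15 other splits that part all pairs (median 3), and in 78 of the 99 others that ignore them (median 2).

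For the bulge against the mean of the others, groups were shuffled within each number with the 2 inner-bulge arrays, which stand apart, left in place. Of 100 such splits 11 gave as many probe sets (real 75, highest other 316) and 30 as many lists (real 13, highest other 16), so chance cannot be excluded for either count. In 1 of the 99 other splits the count was over 3 times the real one (median 9), and its cause was not tested. In the model without the inner-bulge arrays 0 probe sets passed. When those arrays were shuffled too, 1 of 100 splits, the real one, gave as many probe sets (highest other 15) and 8 as many lists (highest other 14), with lists called in 95 of the 99 others (median 6). Splits that ignore the numbers gave as many probe sets in 1 of 100 (highest other 36) and as many lists in 2 of 100 (highest other 13). These splits part the inner-bulge arrays in most cases, so nothing is excluded from them.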

How the results depend on the processing

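The models without the inner-bulge arrays, with the 3' over 5' covariate and with the block on 10 arrays, and the lists without the study's genes, were chosen after the result was seen. No detection calls were used, so dim genes near background are limited by signal over background, and groups of 2 limit 3 comparisons. The naming rule gives 299 pairs of gene and comparison. Of those called, 1 of 4 against the sub-bulge and 1 of 14 against the suprabulbar region (ALAD in both), 51 of 72 against the inner bulge, 0 of 1 against the upper bulge and 0 of 22 against the others passed limma's threshold under every alternative taken singly. Of called lists 1 of 7, 1 of 5, 9 of 16, 1 of 10 and 3 of 13 passed camera's under every alternative but the estimated correlation with the block, and 0 calls reversed. With these together 0 lists passed against the sub-bulge, 0 against the suprabulbar region, 3 against the inner bulge, 2 against the upper bulge and 7 against the others. Over the 299 pairs 7564 values under an alternative kept their side, 235 gained and 408 lost a call, and 58, from 26 uncalled pairs, changed sign. The values below that changed sign are from the 187 pairs kept for the text. These were chosen after it was seen which values changed sign, so the genes named are steadier than the rule's genes as a whole. At the preset correlation the replicate block changed no other list call than those given in the report, and no other call of a gene in a comparison for which the report prints its value. The cause was not tested for these changes, except that leaving out arrays or groups also leaves fewer samples and a filter changes the number tested. The count of 0 for the upper bulge came with 299 probe sets at an unadjusted p under 0.05 in the deposited values, 330 with the higher floor, 317 with only the groups compared, 547 with the fixed block, 404 with array weights and 387 with the covariate, and that of 0 for the others without the inner-bulge arrays with 631, in limma.

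With the 3' over 5' ratio as a covariate the probe sets numbered 18 against the sub-bulge, 0 against the upper bulge, 6 against the suprabulbar region and the sign turned for DIO2 against the upper bulge (0.0569). With array weights the probe sets numbered 17 against the sub-bulge, 0 against the upper bulge, 1142 against the inner bulge, 96 against the suprabulbar region, 130 against the others and the sign turned for CD24 against the upper bulge (0.072). With the deposited values the probe sets numbered 16 against the sub-bulge, 0 against the upper bulge and the sign turned for TFRC against the sub-bulge (-0.00882), PHLDA1 against the inner bulge (-0.0951), CD34 against the inner bulge (-0.0765). With a trended and robust prior the probe sets numbered 15 against the sub-bulge. With an estimated correlation the lists numbered 1 against the sub-bulge, 2 against the upper bulge, 9 against the inner bulge, 1 against the suprabulbar region. With the fixed replicate block the probe sets numbered 66 against the sub-bulge, 0 against the upper bulge, 115 against the suprabulbar region, 162 against the others and the sign turned for KRT15 against the upper bulge (0.27), DIO2 against the upper bulge (0.30), PHLDA1 against the inner bulge (-0.0983). With the replicate block on the bulge and sub-bulge arrays alone the probe sets numbered 32 against the sub-bulge. With the higher floor the probe sets numbered 24 against the sub-bulge, 0 against the upper bulge, 36 against the suprabulbar region. With the mean of probe sets the sign turned for TFRC against the sub-bulge (-0.0656), CD24 against the upper bulge (0.13). With no filter the probe sets numbered 3 against the sub-bulge, 3 against the upper bulge, 6 against the suprabulbar region, 31 against the others. With only the groups compared the probe sets numbered 1 against the sub-bulge, 0 against the upper bulge, 1203 against the inner bulge, 5 against the suprabulbar region. With the random replicate block the probe sets numbered 57 against the sub-bulge, 90 against the suprabulbar region, 209 against the others and the sign turned for KRT15 against the upper bulge (0.0935), DIO2 against the upper bulge (0.13), PHLDA1 against the inner bulge (-0.0465). With the stricter filter the probe sets numbered 18 against the sub-bulge, 124 against the others. Without the inner-bulge arrays the probe sets numbered 2 against the sub-bulge, 2 against the upper bulge, 0 against the others and the lists numbered 5 against the others.

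Leaving out 1 array in turn, the probe sets numbered 1 to 42 against the sub-bulge, 0 to 2 against the upper bulge, 900 to 2223 against the inner bulge, 3 to 49 against the suprabulbar region, 20 to 148 against the others, and the lists 4 to 10 against the sub-bulge, 6 to 10 against the upper bulge, 11 to 17 against the inner bulge, 5 to 7 against the suprabulbar region, 12 to 15 against the others; the lists numbered 4 against the sub-bulge without bulge array 5, and 6 against the upper bulge without upper-bulge array 4 or 5. Values whose sign turned ranged as follows: TFRC against the sub-bulge -0.0372 to 0.18, KRT15 against the upper bulge -0.18 to 0.0911, DIO2 against the upper bulge -0.47 to 0.43, WIF1 against the upper bulge -0.14 to 0.17, DKK3 against the upper bulge -0.44 to 0.10, CD24 against the upper bulge -0.14 to 0.0824, PHLDA1 against the inner bulge -0.46 to 0.46, FST against the inner bulge -1.03 to 0.33, CD34 against the inner bulge -0.17 to 0.27.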

Other observations

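No tests here were chosen after the result was seen. Markers of pigment cells, vessels, immune cells and nerve did not pass the list test in any comparison without the block. The median log2 difference and adjusted p of the melanocyte list were 0.05 (0.892) against the sub-bulge, 0.21 (0.227) against the upper bulge, 0.10 (0.327) against the inner bulge, 0.31 (0.279) against the suprabulbar region and 0.27 (0.0847) against the others. For the endothelial list they were 0.21 (0.378) against the sub-bulge, -0.07 (0.867) against the upper bulge, -0.21 (0.949) against the inner bulge, -0.14 (0.527) against the suprabulbar region and 0.10 (0.901) against the others. The immune list gave 0.19 (0.351) against the sub-bulge, -0.14 (0.176) against the upper bulge, 0.18 (0.949) against the inner bulge, 0.22 (0.405) against the suprabulbar region and 0.08 (0.648) against the others, and the Schwann cell and nerve list, with 3 measured members, -0.25 (0.449) against the sub-bulge, 0.03 (0.259) against the upper bulge, 1.02 (0.782) against the inner bulge, -0.45 (0.279) against the suprabulbar region and 0.09 (0.864) against the others. Hair shaft genes gave 0.06 (0.729) against the sub-bulge, 0.03 (0.584) against the upper bulge, -0.01 (0.782) against the inner bulge, -0.26 (0.0717) against the suprabulbar region and 0.00 (0.648) against the others, and inner root sheath genes, with 4 measured members, 0.09 (0.769) against the sub-bulge, 0.09 (0.867) against the upper bulge, -0.33 (0.667) against the inner bulge, -0.17 (0.462) against the suprabulbar region and -0.14 (0.643) against the others.

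Notch genes gave 0.04 (0.729) against the sub-bulge, 0.08 (0.259) against the upper bulge, 0.10 (0.949) against the inner bulge, 0.07 (0.759) against the suprabulbar region and 0.16 (0.648) against the others, and Wnt target genes -0.24 (0.0532) against the sub-bulge, -0.02 (0.351) against the upper bulge, 0.15 (0.434) against the inner bulge, -0.21 (0.653) against the suprabulbar region and 0.03 (0.648) against the others. Interferon response genes gave 0.03 (0.944) against the sub-bulge, -0.17 (0.611) against the upper bulge, -0.08 (0.977) against the inner bulge, -0.10 (0.462) against the suprabulbar region and -0.02 (0.648) against the others, and cell cycle inhibitors -0.10 (0.729) against the sub-bulge, 0.20 (0.141) against the upper bulge, -0.25 (0.726) against the inner bulge, 0.08 (0.462) against the suprabulbar region and -0.06 (0.864) against the others. The 4 genes that the study reported as lowered in the bulge gave -0.33 (0.351) against the sub-bulge, 0.03 (0.351) against the upper bulge, -0.28 (0.434) against the inner bulge, -0.65 (0.14) against the suprabulbar region and -0.24 (0.0847) against the others; the study chose them on these samples. Among them CD34, known from the mouse bulge, was at -0.93 ± 0.27 against the sub-bulge (adjusted p = 0.367) and MCAM at -0.74 ± 0.23 (0.405), both lower in 5 of 5 pairs, while CD24 was at 0.67 ± 0.27 (0.666), higher in 5 of 5 pairs and so on the other side from the study's list. TFRC was nearly level at 0.08, so 2 of the 4 genes were above 0. Members of the lists in these paragraphs passed over all genes in 2 comparisons. Against the inner bulge 3 of 9 melanocyte, 1 of 11 hair shaft and 2 of 8 Wnt target genes were higher. There 3 of 15 immune genes were higher and 1 lower, 2 of 12 interferon response genes higher and 1 lower, and 1 each higher and lower of 10 Notch genes, 8 cell cycle inhibitors and the 4 genes the study picked as lowered. Against the others 1 melanocyte gene and 1 cell cycle inhibitor were higher, the latter being GAS1, also in the mouse bulge and hedgehog lists. KRT19 was left out by the filter on dim probe sets, with mean log2 levels of 5.16 in the bulge, 5.16 in the sub-bulge, 5.67 in the upper bulge, 2.59 (the floor) in the inner bulge and 5.21 in the suprabulbar region.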
